A study of Homo sapiens with 8 samples.

How the data were processed

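ChIP-seq was carried out on GM12878 cells, per the labels, with antibodies against NIPBL, SMC1A and MED1. Each was done on 2 replicates, and 2 whole cell extract libraries served as input. Per the labels' protocols, the cells were crosslinked with 1% formaldehyde for 10 min and quenched with 125 mM glycine for 5 min before sonication and immunoprecipitation. The submitters' processing notes name Trimmomatic 0.33, BWA 0.7.12 and MACS2 2.1.0 and the build hg19, and their settings are not given in the sources used here. Per the labels, the authors called peaks on each ChIP library alone against the pool of both whole cell extracts. A peak of 1 replicate was therefore called without knowledge of the other, while all 6 lists share the same control.

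The deposited files are peak lists with 1 row per summit. The deposited fold enrichment is a linear ratio of the signal at the summit to the local control estimate, per the layout the peak caller writes. The deposited −log10 p and −log10 q values give the strength of evidence at the summit. The smallest −log10 q in any list was 1.302, just past a q-value of 0.05. The deposited score column was the whole part of 10 times −log10 q in at least 99.98% of peaks of each list and was not used further. The deposited summit offset, counted in bp from the start of the peak, gave the summit positions. Files hold no read totals.

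Depth was recovered in relative terms. The fold enrichment and the p-value of a peak together fix the fragment pileup at the summit and the control estimate. These were solved for each peak, and in at least 99.48% of peaks of each list a solution was found. The pileups solved came out as whole numbers within 0.05. On 3000 simulated peaks the step recovered 100% of pileups within 0.05. These peaks were made with the same formulas, so the check covers the algebra and not how the caller wrote its values. The shortest peak was 200 bp in all 6 lists and 574 to 2234 peaks had exactly that width, so the same fragment length was taken to apply to each library. The lowest control estimate is then proportional to depth. Relative to the deepest library, MED1 replicate 1, depth was 0.965 and 0.820 for NIPBL replicates 1 and 2, 0.752 and 0.743 for SMC1A, and 0.755 for MED1 replicate 2. The step assumes that the caller left the ChIP libraries unscaled, as the whole pileups need. Median pileups at summits were 27 to 38 fragments, and the lowest pileup in a list was 7 to 11 fragments, below which no binding was detected. More fragments were needed for a call where the control estimate was higher. The lowest control estimates were 1.76 to 2.375, while their medians over called peaks were 4.09 to 7.50, so weak binding above those lowest pileups could also be missed.

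Rows alike in both interval and summit were counted once. No peaks of the same list then overlapped, so each peak had 1 summit. Chromosomes 1 to 22 and X were used. Peaks on other sequences were left out, and all but those on chromosome Y were counted. A region of a factor is the merge of overlapping peaks of its 2 replicates, and the regions used were found in both. An overlap of at least 1 bp counted as shared. Expected overlap came from 1000 circular shifts of the query regions along each chromosome, with Benjamini-Hochberg adjustment over the 6 ordered pairs of factors. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. NIPBL at SMC1A regions with and without MED1 was compared by Fisher's exact test over SMC1A regions. Coverage of NIPBL regions by the MED1 and the SMC1A libraries was compared by an exact permutation test over the 4 libraries. NIPBL peak strength was compared between classes by a permutation test with 100000 resamples of the median percentile of fold enrichment within each NIPBL list, adjusted over 3 contrasts and 2 libraries. The overlap step was tested on simulated regions: with 25% and 60% of 10000 regions planted on SMC1A regions it measured 26.2% and 60.6%, where 26.2% and 60.6% were expected with chance overlaps. Of 20 random sets with nothing planted, 1 was called at 0.05. The expected shares used the chance share of the same shifts, and the random regions were scattered along each chromosome, unlike the clustered NIPBL regions.

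NIPBL regions at most 12.5 kb apart were stitched into clusters. The named regions followed a rule written before the data were examined: the 15 strongest NIPBL regions with MED1 and SMC1A, the 5 strongest in each other class, and the 10 clusters with most NIPBL regions, where strength is the mean over both replicates of the percentile of fold enrichment. Values are given for the first 6, 2, 3 and 2 regions with both partners, MED1 alone, SMC1A alone and neither, and the others are summarised. The single MED1 regions named for their width, the counts by strength, width and chromosome, the comparison of MED1 regions by SMC1A, the clustering of MED1 and SMC1A, the matching on width in bins of 50 bp, summit distances and the recovery of depth were chosen after the data were seen.

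Alternatives fixed before the data were examined were an overlap of at least 50% of the shorter region, summits at most 200 bp apart, only peaks with −log10 q of at least 5, the top 15357 peaks by −log10 p in every library, −log10 p in place of fold enrichment as the strength of NIPBL peaks, regions found in either replicate, each library left out in turn, replicates compared within the same number, and local shifts of 50 to 500 kb. Promoter shares, occupancy of gene lists and sequence motifs had been planned and were not run, since the gene table at hand is on another assembly (GRCh38.p14) and no sequence of hg19 was used here. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.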

Results

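The series mapped 3 chromatin proteins in GM12878, an established lymphoblastoid cell line derived from B lymphocytes. NIPBL loads cohesin onto DNA and is the gene most often mutated in Cornelia de Lange syndrome, a developmental disorder that gives the series its title. SMC1A is a subunit of the cohesin ring, which holds DNA in loops, and is also mutated in the syndrome. MED1 is a subunit of Mediator, the complex that links transcription factors at enhancers to RNA polymerase II. Each protein was profiled by ChIP-seq, in which crosslinked chromatin is immunoprecipitated with an antibody and the recovered DNA is sequenced. There were 2 libraries per protein, and 2 whole cell extract libraries that served together as the control for every peak list. The cells were untreated, so the implied question is where the 3 proteins lie together and where they lie apart. No label says that replicates came from separate cultures, so the spread between them may be technical.

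The NIPBL lists held 21422 and 15357 peaks on chromosomes 1 to 22 and X (replicates 1 and 2). The SMC1A lists held 56510 and 68228, and the MED1 lists 18131 and 45046. SMC1A peaks stood highest above the control, with a median fold enrichment within the list of 8.61 and 7.53. The medians were 3.88 and 4.08 for NIPBL and 3.81 and 4.82 for MED1. Fold enrichments are the authors' values for single peaks and are used here to describe and rank peaks within a list. Read totals were not used here. Relative depth recovered from the peak values ran from 0.743 in SMC1A replicate 2 to 1.00 in MED1 replicate 1, so the 3 longest lists came from the 3 shallowest libraries. All intervals are exact 95% binomial intervals that cover counting error only.

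SMC1A peaks recurred most evenly between replicates. Of the shorter SMC1A list 92.0% overlapped the longer (interval 91.8 to 92.2), and 75.6% the other way (75.3 to 75.9). For NIPBL, 79.3% of replicate 2 peaks overlapped replicate 1 (78.6 to 79.9), and 55.6% of replicate 1 peaks overlapped replicate 2 (54.9 to 56.3). MED1 replicate 1 was nested almost wholly in replicate 2, at 99.0% (98.8 to 99.1), whereas 33.6% of replicate 2 peaks overlapped replicate 1 (33.1 to 34.0). Regions found in both replicates numbered 11635 for NIPBL, 51020 for SMC1A and 15007 for MED1. Their median widths were 473, 415 and 769 bp. MED1 regions over 5000 bp numbered 155, against 5 for NIPBL and 3 for SMC1A. Peaks wider than 2 kb numbered 233 in MED1 replicate 1 and 1227 in replicate 2.

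Most NIPBL regions overlapped MED1, and most overlapped SMC1A. Of the 11635 NIPBL regions, 70.2% overlapped a MED1 region (69.4 to 71.1) and 62.5% an SMC1A region (61.6 to 63.3). From the other side, 49.3% of MED1 regions (48.5 to 50.1) and 14.3% of SMC1A regions (14.0 to 14.6) overlapped NIPBL. MED1 and SMC1A shared 52.2% of MED1 regions (51.4 to 53.0) and 17.5% of SMC1A regions (17.1 to 17.8). Each of these 6 shares lay above its expectation from 1000 circular shifts along the chromosomes (permutation test, two-sided, p = 0.001 and adjusted p = 0.001, the smallest these shifts can give). NIPBL regions met MED1 80.4 times and SMC1A 33.3 times as often as shifted regions did. Local shifts of 50 to 500 kb, which keep regions in their neighbourhood, lowered these ratios to 36.5 and 19.7 (permutation p = 0.001). Neither kind of shift was restricted to stretches open to ChIP signal, so lists that share only such stretches could also pass. The p-values and ratios therefore cannot tell binding together from shared accessible DNA or from signal common to every ChIP library. The MED1 ratio fell to 51.9 without MED1 replicate 1, rose to 107 without MED1 replicate 2 and was 52.1 with regions found in either replicate. The SMC1A ratio stayed between 31.1 and 36.8 with 1 library left out and fell to 19.1 with the same number of top peaks in every library. With summits at most 200 bp apart the ratios were 179 and 60.5. With the same number of top peaks in every library, the share of NIPBL regions with SMC1A was 11.7% and the share with MED1 was 64.5%. That setting removes most SMC1A peaks by construction. The same setting lowered the share of MED1 regions with SMC1A to 5.91%, of SMC1A regions with MED1 to 4.53% and of SMC1A regions with NIPBL to 8.07%, each still above its shifts (permutation p = 0.001). Regions found in either replicate raised the share of SMC1A regions with MED1 to 35.3% and with NIPBL to 22.8%. Without MED1 replicate 1, 22.9% of MED1 regions overlapped NIPBL, 32.7% overlapped SMC1A, and 30.2% of SMC1A regions overlapped MED1.

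Sorted by both partners, 5564 NIPBL regions held MED1 and SMC1A (47.8%, 46.9 to 48.7). MED1 alone accompanied 2606 (22.4%, 21.6 to 23.2), SMC1A alone 1702 (14.6%, 14.0 to 15.3), and neither 1763 (15.2%, 14.5 to 15.8). Of the 1763 regions with neither, 89.1% overlapped a MED1 or SMC1A peak that was called in 1 replicate, which left 192 NIPBL regions, or 1.65%, away from every peak of the other factors. Such a MED1 peak was met by 1515 of the 1763 and such an SMC1A peak by 735. MED1 replicate 1 was nested almost wholly in replicate 2, so the 1.65% leaned on the longer MED1 list. SMC1A regions showed the opposite makeup, since 40432 of 51020 (79.3%, 78.9 to 79.6) held neither NIPBL nor MED1. MED1 regions fell between, with 34.5% (33.8 to 35.3) holding both partners and 33.0% (32.2 to 33.8) holding neither. The MED1 and SMC1A classes were not recounted under the alternatives. The share of MED1 regions with both could be at most 22.9% without MED1 replicate 1, the share that overlapped NIPBL. It could be at most 5.91% with equal numbers of top peaks, the share that overlapped SMC1A. Single libraries set much of the NIPBL classes. The share with neither was 2.21% without MED1 replicate 1, 28.2% without NIPBL replicate 2 and 9.96% without SMC1A replicate 1. The share with SMC1A alone fell to 3.95% without MED1 replicate 1, and that with MED1 alone was 35.3% without MED1 replicate 1 and 10.8% without SMC1A replicate 1.

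**Figure D1:**
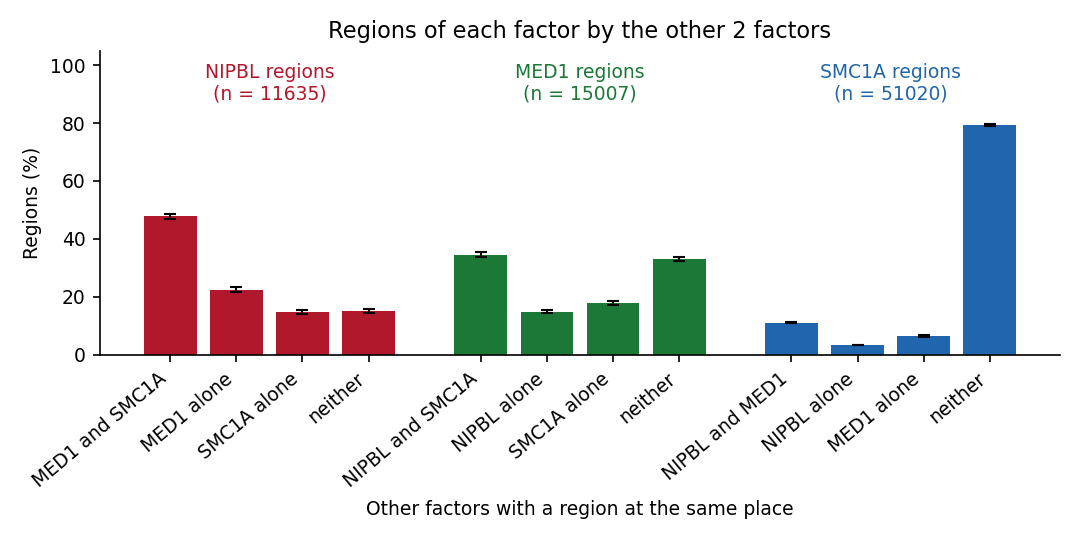
Share of the regions of each factor (y axis, percent of regions found in both replicates) that also held regions of the other factors (x axis). Bars are shares over 11635 NIPBL, 15007 MED1 and 51020 SMC1A regions, error bars are exact 95% binomial intervals, and 79.3% of SMC1A regions held neither NIPBL nor MED1.

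Whether MED1 or SMC1A covered more of NIPBL was not resolved by the 2 libraries of each. The MED1 libraries covered 69.0% and 93.9% of NIPBL regions, a mean of 81.4% ± 17.6 (SD, n = 2). The SMC1A libraries covered 65.1% and 79.2%, a mean of 72.2% ± 9.97 (SD, n = 2). The difference of 9.26 percentage points had p = 0.667 in a two-sided exact permutation test, in which n = 2 per factor cannot give less than 0.333. It was 58.8 points with equal numbers of top peaks (exact permutation p = 0.333), where the SMC1A lists lose most of their peaks by construction. It turned to -3.16 points without MED1 replicate 2, and was 21.7 without MED1 replicate 1, 2.21 without SMC1A replicate 1 and 16.3 without SMC1A replicate 2.

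At SMC1A regions, NIPBL was more frequent where MED1 was present. Of 8912 SMC1A regions with MED1, 63.2% held NIPBL (62.2 to 64.2), against 3.98% (3.8 to 4.17) of the 42108 without MED1. The second share was 1.26% without MED1 replicate 1 and 8.12% without NIPBL replicate 2, where the first was 44.5% and 75.5%. The odds ratio was 41.4 (Fisher's exact test, two-sided, p below 1e-300, with regions treated as independent, which neighbouring regions are not). It was 62.9 without MED1 replicate 1 and 19.3 with equal numbers of top peaks. At MED1 regions the difference by SMC1A was smaller in size, with an odds ratio of 4.36. NIPBL was held by 66.1% of 7840 MED1 regions with SMC1A (65.0 to 67.2), against 30.9% of 7167 without it (29.9 to 32.0). With equal numbers of top peaks this second odds ratio was 1.17 (Fisher's exact test, two-sided, p = 0.062). The difference between the odds ratios was not tested. Neither comparison was matched on width. SMC1A regions with NIPBL had median widths of 596 bp with MED1 and 643 bp without it. Those without NIPBL had 460 and 394 bp. Like the shifts, these odds ratios cannot tell binding together from shared accessible DNA or from signal common to every ChIP library.

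SMC1A peaks at MED1 regions were weak ones, with or without NIPBL. Their median fold enrichment in the 2 SMC1A libraries was 4.37 and 5.32 at regions with NIPBL and MED1, and 4.38 and 5.14 at regions with MED1 and no NIPBL. At SMC1A regions with neither it was 11.5 and 12.9. SMC1A regions with NIPBL and no MED1 were the strongest class, at 14.9 and 17.4, but formed a broad group whose quartiles in replicate 1 were 4.18 and 24.8. In this class no MED1 means no MED1 region found in both replicates. Counted against MED1 replicate 2 alone, SMC1A regions without MED1 held NIPBL in 1.26%, against 3.98% as classed here. Most of this class therefore overlapped a peak of MED1 replicate 2. Across each list, the share of MED1 peaks with a NIPBL region went from 24.8% in the weakest 20% to 80.7% in the strongest in replicate 1, and from 5.05% to 62.1% in replicate 2. Along the SMC1A lists it went the other way, from 33.8% to 3.96% in the class next to the strongest and 8.83% in the strongest in replicate 1. In replicate 2 it went from 23.8% to 4.09% and then 8.38%. The strongest SMC1A peaks were also wider than the class next to them, with medians of 475 against 385 bp and 488 against 382 bp. Shares along the MED1 lists were not matched on width. The change from the weakest to the strongest 20% averaged -20.2 points over the SMC1A libraries, -10.1 with peaks ranked by −log10 p, and turned to 4.44 among equal numbers of top peaks.

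**Figure D2:**
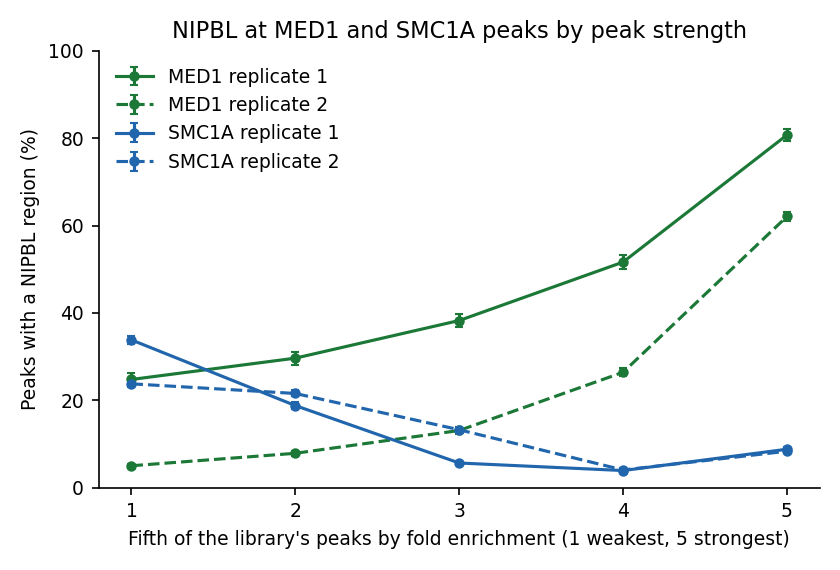
Share of MED1 and SMC1A peaks with a NIPBL region (y axis, percent) in 5 classes of 20% of each library's peaks, ordered by fold enrichment within the list (x axis). Lines join the classes of one library, error bars are exact 95% binomial intervals, and NIPBL reached 80.7% and 62.1% of the strongest MED1 peaks against 8.83% and 8.38% of the strongest SMC1A peaks.

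NIPBL peaks with both partners were stronger and wider than peaks with neither, and most of the difference in strength went with width. Width and fold enrichment are read from the same signal, so matching on width can also remove a real difference in strength. All peaks of each NIPBL list were used here, whether or not they were found in the other replicate. Peaks with both and with neither numbered 7077 and 6046 in replicate 1, and 6400 and 3002 in replicate 2. Within the list, peaks with MED1 and SMC1A had a median percentile of fold enrichment 22.4 points above peaks with neither in NIPBL replicate 1 and 19.4 points above in replicate 2. Both differences passed a two-sided permutation test with 100000 resamples (p = 1e-05 and adjusted p = 1e-05, the smallest these resamples can give). Peaks with SMC1A alone lay 8.78 and 8.54 points above (permutation p = 1e-05 and adjusted p = 1e-05 in each). Peaks with MED1 alone lay 0.131 and 1.403 points above, which did not pass (permutation p = 0.970 and 0.248, adjusted p = 0.970 and 0.298). Ranked by −log10 p they lay 12.8 points above on average over both libraries and passed (permutation p = 1e-05), and peaks with both lay 34.9 points above. Median widths were 465 and 395 bp with both partners and 265 and 252 bp with neither. With peaks matched on width, the difference in mean percentile between both and neither fell from 15.5 to 1.89 points in replicate 1 and from 14.1 to 0.206 in replicate 2, where it no longer passed (permutation p = 0.753), while in replicate 1 it still did (permutation p = 0.00087, adjusted p = 0.0013). With MED1 alone it turned to -2.59 and -2.08 points, which passed in the opposite direction (permutation p = 1e-05 and 0.00177, adjusted p = 3e-05 and 0.00212), and with SMC1A alone it kept 4.37 and 3.74 points (permutation p = 2e-05 at most). At regions found in both NIPBL replicates, the strongest peak had a median percentile of 73.5 with both partners and 56.95 with neither in replicate 1. In replicate 2 these medians were 65.7 and 47.4. Peaks of one library are not independent replicates.

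NIPBL was most frequent at the broadest MED1 regions. It was present at 39.6% of the 2966 MED1 regions up to 500 bp wide (37.8 to 41.4) and at 99.4% of the 155 wider than 5000 bp (96.5 to 99.98). SMC1A rose with width as well, from 40.7% (38.9 to 42.5) to 93.5% (88.5 to 96.9). A wider region has more room for an overlap, and no correction was made for width. Peaks wider than 2 kb numbered 1227 in MED1 replicate 2 and 233 in replicate 1. The broad classes therefore rested largely on replicate 2, whose widest peak was 20758 bp against 12440 bp in replicate 1. The widest MED1 region, on chromosome 14 from 22943466 to 22964223, held 3 NIPBL and 5 SMC1A regions. The second, on chromosome 21 from 26932133 to 26947150, held 2 of each. The third, on chromosome 8 from 128216479 to 128230889, held 6 NIPBL and 4 SMC1A regions.

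**Figure D3:**
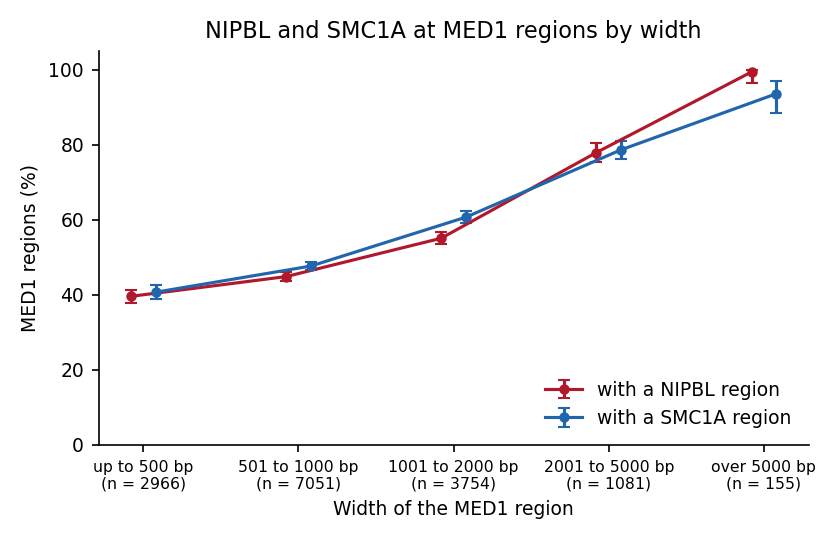
Share of MED1 regions with a NIPBL or an SMC1A region (y axis, percent) by width of the MED1 region (x axis, classes in bp). Points are shares, error bars are exact 95% binomial intervals, and the share with NIPBL went from 39.6% of the narrowest class to 99.4% of the widest. Peaks wider than 2 kb numbered 233 and 1227 in MED1 replicates 1 and 2.

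The strongest NIPBL regions with both partners lay on 9 chromosomes and were 583 to 3480 bp wide, against a median of 580 bp for all NIPBL regions with both partners. Positions are 1-based on hg19, and no gene annotation of that build was used here, so regions are named by position. The first of the 15 named, on chromosome 13 from 114832643 to 114833796, had NIPBL fold enrichments of 21.5 and 18.9 in replicates 1 and 2, MED1 of 10.5 and 27.1, and SMC1A of 5.08 and 9.39. The second, on chromosome 7 from 55601706 to 55603115, had NIPBL of 18.8 and 16.8 and MED1 of 18.0 and 38.0. The third, on chromosome 13 from 42951320 to 42953430, had NIPBL of 16.2 and 15.6. The fourth, on chromosome 3 from 124859457 to 124861072, had NIPBL of 24.0 and 14.8. The fifth, on chromosome 1 from 235145515 to 235148994, was the widest of the 15 at 3480 bp. On chromosome X from 130845008 to 130845655, the sixth region had the highest SMC1A of the 15, at 20.8 and 22.8.

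Strong NIPBL also occurred with a single partner or with none, where a partner is a region found in both of its replicates. A partner peak of 1 replicate may still lie at these positions, as at 89.1% of all NIPBL regions with neither. The named regions were not checked for such peaks. With MED1 and no SMC1A, the strongest region lay on chromosome X from 9309333 to 9310293 (NIPBL 14.1 and 15.0, MED1 6.14 and 11.1) and the next on chromosome 15 from 70391742 to 70392436 (NIPBL 11.9 and 11.6). With SMC1A and no MED1, the strongest lay on chromosome 2 from 171092320 to 171092874 (NIPBL 11.2 and 11.04, SMC1A 22.1 and 30.9). The next, on chromosome 6 from 137592482 to 137593190, had SMC1A of 30.2 and 31.2. By contrast the third, on chromosome 1 from 31341925 to 31342297, had SMC1A of 4.52 and 3.81 with NIPBL of 9.16 and 12.2. With neither partner, the strongest lay on chromosome 9 from 99003578 to 99004095 (NIPBL 12.3 and 10.1) and the next on chromosome 8 from 144679579 to 144679869 (NIPBL 11.96 and 9.63). The other named regions with MED1 alone lay on chromosomes 11, 8 and 20, those with SMC1A alone on chromosomes 17 (SMC1A 12.4 and 16.5) and 15 (SMC1A 3.73 and 3.76), and those with neither on chromosomes 3, 19 and 17.

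NIPBL regions gathered in clusters about as often as MED1 regions and far more often than SMC1A regions. After stitching of neighbouring regions, 55.1% of NIPBL regions lay in clusters of at least 2. Random sets of MED1 regions of the same number gave 51.0% ± 0.322, and of SMC1A regions 19.4% ± 0.423 (SD over 100 draws each). With only peaks of −log10 q of at least 5, the shares at equal region numbers were 47.4% for NIPBL, 44.5% for MED1 and 13.0% for SMC1A. Without NIPBL replicate 2 they were 57.3%, 57.5% and 23.9%, so the order of NIPBL and MED1 was not kept. There were 245 clusters of at least 5 NIPBL regions and 20 of at least 10. In clusters of at least 5, 70.1% of NIPBL regions held both partners, against 33.4% of regions that stood alone.

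The cluster with most NIPBL regions lay on chromosome X from 130862362 to 130956845, a span of 94.5 kb. It held 19 NIPBL regions, 14 MED1 regions and 20 SMC1A regions, and all 19 NIPBL regions held both partners. The next clusters lay on chromosome 9 from 132750941 to 132805734 with 16 NIPBL regions, of which 6 held both partners, and on chromosome 3 from 98241228 to 98292609 with 14, of which 6 did. On chromosome 6 from 290987 to 342494, all 13 NIPBL regions held both. A cluster of 12 on chromosome 8, from 128190665 to 128228746, reached into the third widest MED1 region. The other 5 of the 10 named clusters lay on chromosomes 12, 15, 16 (with 2) and 17 and held 11 or 12 NIPBL regions each.

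**Figure D4:**
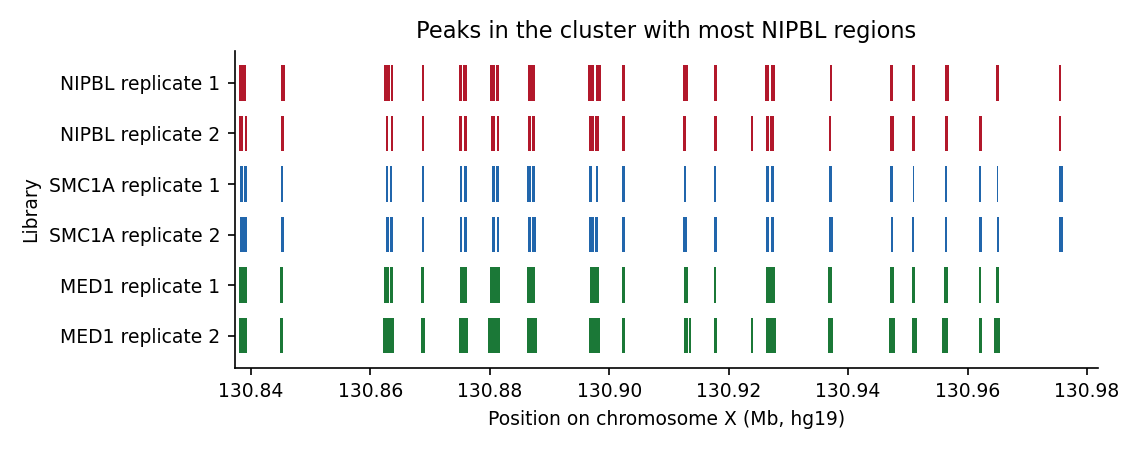
Peaks of the 6 libraries (rows) in the cluster with most NIPBL regions and 25 kb to each side (x axis, position on chromosome X in Mb, hg19). Each bar is a peak drawn to scale, and inside the cluster NIPBL had 19 and 22 peaks, SMC1A 20 and 20, and MED1 17 and 16 in replicates 1 and 2.

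The factors also differed in how they spread over chromosomes. Relative to SMC1A, MED1 regions were over-represented on chromosomes 19 (share ratio 1.35), 17 (1.302), 22 (1.25), 21 (1.24) and 16 (1.19), and under-represented on chromosomes 4 (0.741), X (0.759), 18 (0.811), 13 (0.845), 7 (0.881) and 3 (0.911). All 11 passed Fisher's exact test (two-sided, adjusted p at most 0.0314 over 46 tests) with the same direction in each of the 4 pairs of libraries. NIPBL regions were over-represented on chromosome 6 (1.22, Fisher's exact test, adjusted p = 2.42e-06) and under-represented on chromosomes X (0.794), 11 (0.835) and 4 (0.873) by the same criteria. Chromosome 16 passed Fisher's exact test for NIPBL (1.16, adjusted p = 0.0211) but its direction was not shared by all 4 library pairs. Regions of one cluster are not independent, so these p-values are too small.

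**Figure D5:**
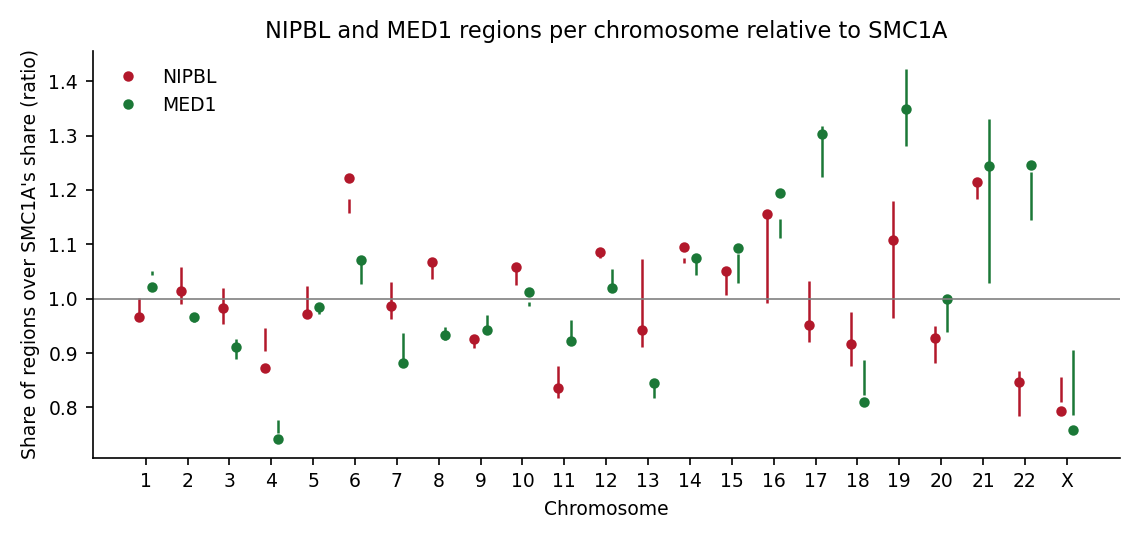
Share of NIPBL and MED1 regions on each chromosome divided by the share of SMC1A regions there (y axis, ratio; x axis, chromosome). Dots are regions found in both replicates, vertical lines span the 4 pairs of single libraries, and MED1 reached 1.35 on chromosome 19 and NIPBL 1.22 on chromosome 6.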

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

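The comparisons by peak strength were made only after the data had been seen. The tests of the explanations below were set down before their results were known.

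The share of peaks with NIPBL moved in opposite directions along the MED1 and the SMC1A lists. From the weakest to the strongest 20% of peaks it changed by 55.9 percentage points in MED1 replicate 1 and 57.0 in replicate 2, and by -25.0 and -15.4 points in SMC1A replicates 1 and 2. Both libraries of one factor moved one way and both of the other the opposite way, and this difference was not itself tested. Among equal numbers of top peaks, which keep only the strongest SMC1A peaks, the SMC1A change turned to 4.44 points. The MED1 change was not matched on width, although NIPBL was present at 39.6% of the narrowest and 99.4% of the widest class of MED1 regions.

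SMC1A peaks were weaker at regions with NIPBL and MED1 than at regions with neither, and as weak at regions with MED1 and no NIPBL (median summit pileups of 28 and 33, against 30 and 36 with both and 51 and 57 with neither), so the pattern was not particular to regions with NIPBL. A higher control estimate at those regions would lower the fold enrichment without less SMC1A signal. The control estimate was higher there, with medians of 6.11 and 6.04 against 3.76 and 3.72 in SMC1A replicates 1 and 2, yet the uncorrected pileup at summits was also lower, at 0.588 and 0.632 times that of regions with neither, which argues against the control as the whole cause. Signal common to every ChIP library may still contribute: across those regions SMC1A pileup followed MED1 pileup with Spearman's rho of 0.333 to 0.358 over 4 library pairs, against 0.837 between the SMC1A replicates, and this value lay between the bounds set in advance, so it cannot be told apart from cohesin bound at those regions. Regions are not independent replicates, and no biological explanation was tested, since the design has a single cell line without treatment.

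In both SMC1A libraries the share with NIPBL rose again in the strongest 20% of peaks, by 4.88 and 4.29 points over the class next to it. Wider peaks may account for this: with peaks matched on width in bins of 50 bp, the differences were -0.590 and -1.38 points, or -12.1% and -32.3% of their former size. Width and fold enrichment are read from the same signal, so the matching cannot separate an effect of width from one of strength. Signal of the strongest SMC1A sites carried into the NIPBL libraries also stays open. NIPBL pileup followed SMC1A pileup at strong SMC1A regions with NIPBL and no MED1 region found in both replicates. Spearman's rho across regions was 0.410 to 0.466 over 4 library pairs. NIPBL bound in proportion to cohesin would give the same relation, so neither the technical nor the biological reading was singled out.

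Each list also held peaks outside chromosomes 1 to 22, X and Y, called above the pooled whole cell extracts and used in no comparison. They numbered 39 and 12 in NIPBL replicates 1 and 2, 53 and 57 in SMC1A, and 29 and 37 in MED1. Unplaced contig gl000220, which carries ribosomal DNA, held 22 and 4 of them in NIPBL, 10 and 9 in SMC1A, and 12 and 10 in MED1. Mitochondrial peaks numbered 8 and 3, 5 and 5, and 9 and 8 in the same order.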

How the results depend on the processing

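The matching on width and the alternatives for clusters, for ratios over chance (local shifts aside), for the 20% strength classes of MED1 and SMC1A peaks and for MED1 regions by SMC1A were added after the data were seen. All 72 alternative values of the overlap between factors kept their direction, as did all 72 ratios over chance. All 12 odds ratios for NIPBL at SMC1A regions by MED1 did so too. Values that left out a library of a factor outside the pair could not move beyond the randomness of the shifts. Ratios other than those from local shifts came from the same shifts as the overlap values, so they add no separate support. With equal numbers of top peaks, the share of MED1 regions with SMC1A was 5.91% and of SMC1A regions with MED1 4.53%. With regions found in either replicate, 35.3% of SMC1A regions held MED1 and 22.8% held NIPBL. Of 12 alternative values of peak strength 9 kept their direction and side of the threshold. Those that left out a NIPBL library were the values of the other library, already part of the reported mean, so they add no separate support. Every change came from −log10 p as the strength or from matching on width. NIPBL peaks with MED1 alone passed it with −log10 p as the strength (12.8 points). Matching on width left a mean of 1.05 points between both and neither, which passed in replicate 1 (1.89 points, permutation p = 0.00087) and not in replicate 2 (0.206 points, permutation p = 0.753), and turned MED1 alone to -2.34 points, which passed in both libraries. Where a cause is not named below, the cause was not tested. The lowest pileups called, 7 to 11 fragments, limit what a missing peak can show, and more fragments were needed where the control estimate was higher.

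Overlap of the shorter with the longer replicate list, for NIPBL, SMC1A and MED1, was 76.8%, 91.1% and 98.4% with at least 50% of the shorter peak shared, and 71.4%, 89.0% and 76.8% with summits at most 200 bp apart. It was 93.2% for SMC1A and 99.3% for MED1 with −log10 q of at least 5, and 67.0%, 92.4% and 85.8% with equal numbers of top peaks.

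The NIPBL classes moved with most settings. The shares with both partners, MED1 alone, SMC1A alone and neither were 43.2%, 26.0%, 13.3% and 17.5% with −log10 q of at least 5, and 60.2%, 23.9%, 7.85% and 8.08% with regions found in either replicate. They were 3.595%, 60.9%, 8.06% and 27.4% with equal numbers of top peaks, where the SMC1A lists lose most of their peaks by construction. With summits at most 200 bp apart, both partners had 43.2%, SMC1A alone 16.3% and neither 17.8%. With 1 library left out in turn, the shares ranged from 33.0% to 59.4% for both, 10.8% to 35.3% for MED1 alone, 3.95% to 19.8% for SMC1A alone and 2.21% to 28.2% for neither.

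The MED1 minus SMC1A difference ran from -3.16 to 21.7 points with 1 library left out and turned negative only without MED1 replicate 2. The share of NIPBL regions in clusters was 47.4% with −log10 q of at least 5, 52.7% with equal numbers of top peaks, 66.9% with either replicate, and 59.6% to 65.5% with 1 NIPBL library left out. The change in NIPBL share along the SMC1A lists turned to 4.44 points with equal numbers of top peaks, which remove the weaker SMC1A peaks. At MED1 regions, the odds ratio by SMC1A fell short of the threshold with equal numbers of top peaks (1.17, Fisher's exact p = 0.062).

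Replicates of different factors share only a number. Peaks of 2 libraries were merged, and the share of merged regions that held both was taken. With the same number its mean was 16.2% for NIPBL and SMC1A, 33.8% for NIPBL and MED1 and 20.4% for SMC1A and MED1. With the other number it was 16.5%, 37.5% and 18.5%. Within the replicate block the class shares were 50.6%, 20.8%, 12.3% and 16.3%, the MED1 minus SMC1A difference was 8.54 points, and the odds ratio at SMC1A regions was 37.2. Promoter shares, gene list occupancy, motif shares and the restriction to regions away from promoters were not run, for lack of an hg19 annotation and sequence here.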

Other observations

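The summit distances, the depth test and the enrichment test were chosen only after the results were seen. The test at the stricter threshold was set down before its result was known.

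Within the 5564 NIPBL regions that held both partners, summits lay close together, with the summit of the strongest peak taken for each library. The median distance from NIPBL to MED1 summits was 46 to 54 bp over 4 pairs of libraries, and from NIPBL to SMC1A summits 67 to 76 bp. The 2 NIPBL replicates lay a median of 44 bp apart in the same regions, the SMC1A replicates 45 bp and the MED1 replicates 34 bp. The MED1 summit was the nearer one to NIPBL in 53.6% to 59.9% of regions over 8 combinations of libraries, and the SMC1A summit in 39.3% to 45.7%. The order did not hold at 200 bp, within which 80.4% to 81.9% of MED1 and 81.4% to 83.4% of SMC1A summits lay.

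MED1 replicate 2 held 2.48 times the peaks of MED1 replicate 1. Greater depth would need a higher control floor in replicate 2, but the ratio of replicate 2 to replicate 1 was 0.755 at the same fragment length, which argues against depth. Weak calls near the authors' threshold would vanish at a stricter one, but with only peaks of −log10 q of at least 5 the ratio was 2.74. Stronger enrichment in replicate 2 may account for the longer list, as a hypothesis: at 14914 shared regions the summit pileup divided by relative depth was higher in replicate 2 in 99.5%, with a median ratio of 2.08 (quartiles 1.77 and 2.39). What made the enrichment differ was not tested, and the design names no biological difference between the 2 libraries. The consequence for the classes was direct, since 93.9% of NIPBL regions overlapped MED1 replicate 2 and 69.0% overlapped replicate 1.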
